A study of Schizosaccharomyces pombe with 3 samples.

How the data were processed

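H3K9ac chromatin immunoprecipitation was hybridised to 60-mer Agilent tiling arrays for 3 strains of the fission yeast Schizosaccharomyces pombe: wild type, a deletion of alp13, and the asf1-1 allele of asf1. Per the labels, cells grew in rich medium at 30 °C, were fixed at 18 °C in 3% paraformaldehyde, and their DNA was sheared to 500 to 1000 bp. Each strain had 1 array, on which Cy5 carried the immunoprecipitated DNA and Cy3 the whole-cell extract DNA, per the labels' protocols. Both channels were amplified by random-primed PCR before labelling, per the labels.

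The deposited scanner files were made with Agilent Feature Extraction 10.7.3.1, per the file headers and the submitters' processing notes. The deposited processed intensity of each channel was already background-subtracted, detrended across the array and dye-normalised with 1 linear factor per channel, per the file headers. The deposited log ratio column is on a log10 scale, Cy5 over Cy3, and its error column comes from the scanner software's error model, per the file headers. These errors set the noise of the simulations. The genome build of the probe coordinates is not given in the sources used here. The authors' deposited value table has 1 column per array, with column medians over all features of 0.114 for wild type, 0.0849 for the alp13 deletion and -0.0204 for asf1-1. Its scale, centring and direction stayed unknown, because its columns did not follow the arrays they are named for (r of 0.225, 0.528 and -0.58 with the log ratio of the same array). The alp13 deletion column followed the asf1-1 array (r = 0.687) and the wild-type array (r = 0.645) better than its own. Which hybridisation each column holds is thus in doubt, and the assignment of the arrays to strains rests on the labels alone. The value table entered no comparison.

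For each probe the log2 ratio of processed Cy5 to processed Cy3 intensity was computed, and each array was centred on the median of its probes, with no loess or quantile step. Control spots and spots marked as outliers by the scanner software were left out, which kept 43912 of 43993 probes. A change is a mutant's log ratio minus that of wild type, so its sign is relative to the array medians. Before centring, the medians were 0.00 for wild type, 0.41 for the alp13 deletion and 0.17 for asf1-1. Centring moved the median change of all genes from 0.34 to -0.07 in the alp13 deletion and from 0.17 to 0.00 in asf1-1. Centring on the median of intergenic probes put those medians at 1.12 and 0.40. All changes below use the array medians, and differences between probe classes do not depend on the centring.

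The files name no genes and hold no probe sequences, so probes were placed on the ASM294v3 reference. A constant offset was searched within 4000 bp either way. The best offset gave the highest correlation between the reference GC content under each 60-base window and the mean Cy3 signal of all arrays. This placement was chosen after the array coordinates were found to differ from the reference: array chromosome II reaches base 4541560, which is 1756 bases past the end of the reference chromosome. A segment was placed when its best r exceeded the next by at least 0.1 and it held at least 200 probes. The minimum of 200 was added after a segment of 99 probes on chromosome I had passed the margin. On chromosome II the offset was -900 bp left of array base 1616911 and -1800 bp right of it, and all of 30 and 72 blocks of 20000 bp gave the segment's offset within 20 bp. The left end of chromosome III had an offset of -1 bp. In all, 42972 probes were placed. The method was tested on simulated data before use. Gene coordinates below are those of the ASM294v3 annotation, and region coordinates are the array's own. No coordinate was converted for printing, but the assignment of probes to genes rests on these offsets.

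The placed probes cover array bases 1000011 to 3049820 of chromosome II, the last 50 kb of that chromosome, and the first 50 kb of chromosome III. The remaining probes include 824 on an extra contig of 41210 bp. The first 12 kb of that contig matched array bases 2111561 to 2123570 of chromosome II by Cy3 signal (r = 0.964, next best 0.626), and the 239 near-duplicate probe pairs there gave a measure of error within 1 array. The SD of 1 probe's change was 0.133 for the alp13 deletion and 0.0768 for asf1-1.

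A gene's value was the mean over the probes whose middle lies inside it. This was done for the 893 protein-coding genes with 3 or more probes, with a median of 34 probes per gene. The SD given beside a gene's value is across its probes and is not a replicate error. Genes were called higher or lower at a 1.5-fold change (0.585 on the log2 scale). Probes were also classed by position: within 500 bp upstream of a gene, in its first, middle or last part of equal length, within 500 bp downstream, or elsewhere between genes. The 10884 intergenic probes are all placed probes outside protein-coding genes that were kept. They and the class elsewhere between genes hold probes of centromere 2 and of the rDNA end of chromosome III. With 1 array per strain there is no replicate check, no p-value and no standard error, and the number of arrays limits the precision. Of the spots, 99.8% on the wild-type array, 99.7% on the alp13 deletion array and 99.5% on the asf1-1 array were well above background in both channels, and none was saturated. All 3 arrays lay on 1 slide, so no slide batch could be separated.

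Differences between probe classes were set against 10000 random probe lists matched on the mean log ratio, and against 1000 rotations of the gene positions along chromosome II. Regions were set against 10000 random runs of neighbouring probes from the long tiled part of chromosome II outside centromere 2, which holds genes. Gene lists were set against 10000 random lists of the same size matched on the mean log ratio. Percentiles under 2.5 or over 97.5 were taken as outside the central 95%. They describe these arrays and are not p-values. The correlation of the 2 mutants' changes was set against 100 simulations of unchanged groups that share the wild-type array.

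The tests, the gene lists, the alternatives and the rule for naming genes were fixed before the data were examined. The rule took genes with 3 or more probes, all changed in the same direction and well above background in both channels, and with a Cy3 change under 2-fold. From these it took the 8 highest and 8 lowest genes per mutant against wild type and the 5 highest and 5 lowest for asf1-1 against the alp13 deletion. In each described list it took the 2 highest and 2 lowest members, and alp13 and asf1 in every case. The 19 lists were ribosomal protein, histone, glycolysis, stress response, chaperone, meiotic, meiotically upregulated (mug), nitrogen starvation and mating, iron uptake, phosphate uptake, membrane transporter, Tf2 retrotransposon, wtf, Clr6 complex, Asf1 and HIRA, heterochromatin factor, sterol and lipid synthesis, cell cycle and strain marker genes. After the data had been seen, a minimum of 3 measured members was set for a list's percentile, which 12 lists met. The boundaries of centromere 2 (the widest gap between coding genes, from rpb1 to yox1) and of the mat3 region (rpp202 to emc3), the use of the extra contig past its first 12 kb, the left end of chromosome III, and the choice of leading results were also set then.

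The gene and list steps were tested on simulated data with the scanner error of the wild-type and alp13 deletion arrays. All 50 genes changed 2-fold, all 50 changed 3-fold and all 50 changed 4-fold were called. Of 50 genes changed by a smaller fold, below the threshold, 1 was called. Of 693 unchanged genes 18 were called, and of the 622 that share no probe with a changed gene none was called. A list of 20 genes raised 2-fold reached percentile 100.0, and a shift of 0.5 added to gene bodies was recovered as 0.506. These simulations hold only the scanner's spot error and leave out variation between cultures, immunoprecipitations and arrays. They check the computation and do not measure how many calls between strains are false.

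The alternatives fixed in advance were normexp background correction (offset 50), background-subtracted signals without dye normalisation, arrays scaled to 1 spread, centring on intergenic probes, no centring, only probes well above background, the gene median, a minimum of 1 or 5 probes, a 2-fold threshold, lists matched on Cy3, the second part of the gene on a split at its midpoint, and equal noise in the simulation. Median signals replaced mean signals in the first pair, because the files used here have no mean signal column. Added after seeing the data were the Cy5 signal alone, log ratios adjusted for probe GC content, lists matched on gene length, the outer 20 kb of the tiled end of chromosome II, and the rotations. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.

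Centromeres of chromosomes I and III, the other chromosome ends, and 3 short segments of chromosomes I and III that were not placed entered no comparison of genes. The array reaches only 50 kb from the right end of chromosome II, in place of the 100 kb foreseen. Neither alp13 (chromosome I, 1587022 to 1588577) nor asf1 (chromosome III, 1642902 to 1644584) had a probe inside it, so the strain labels could not be checked from the Cy3 signal.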

Results

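Acetylation of lysine 9 of histone H3 (H3K9ac), a mark of active chromatin that histone deacetylases remove, was mapped in growing fission yeast by chromatin immunoprecipitation on tiling arrays. The 3 strains were wild type, a deletion of alp13, which encodes a chromodomain subunit of the Clr6 histone deacetylase complex, and asf1-1, an allele of the gene for the histone chaperone Asf1. Each strain was measured on 1 array of 43993 probes spaced 50 bp apart, most of them on chromosome II. The median Cy3 (whole-cell extract) intensity was 1811 in wild type, 1619 in the alp13 deletion and 1693 in asf1-1, and the median Cy5 (H3K9ac) intensity was 1808, 2101 and 1895 in the same order. Across probes, the log ratios of wild type correlated with those of asf1-1 at r = 0.894 and with those of the alp13 deletion at r = 0.477, and the mutants correlated with each other at r = 0.712. Probes are not independent replicates. No difference below has a replicate check. The series holds no array of total histone H3, so a change in H3 amount cannot be told apart from one in H3K9ac. Which array belongs to which strain rests on the labels alone, since alp13 and asf1 have no probes.

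In wild-type cells, the question was where H3K9ac lay before the mutants were set against it. The mark was high upstream of genes and low in their bodies and in heterochromatin. The median log2 ratio was 0.58 over the 5362 upstream probes and 0.26 in the first part of genes. It was -0.25 over the 9722 probes of the middle part, -0.23 in the last part, -0.05 downstream and -0.18 elsewhere between genes. The class elsewhere between genes also holds probes of centromere 2 and of the rDNA end of chromosome III. The middle part lay 0.84 below the upstream class (difference -0.84), and none of 1000 rotations of the gene positions gave a difference as far from 0. Centromere 2 had a median of -2.20, the mat3 region -2.33, the extra contig past its first 12 kb -2.23 and the last 50 kb of chromosome II -1.24. Some 2-kb bins of that contig lay above the array median, among them the bin from 18000 at 0.66. Medians of gene lists ran from -0.56 for the Clr6 complex genes to 0.14 for the mug genes, with ribosomal protein genes at -0.10 and glycolysis genes at 0.04. On Cy5 brightness alone, which compares different probe sequences, the middle part lay above the upstream class by 0.49.

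**Figure D1:**
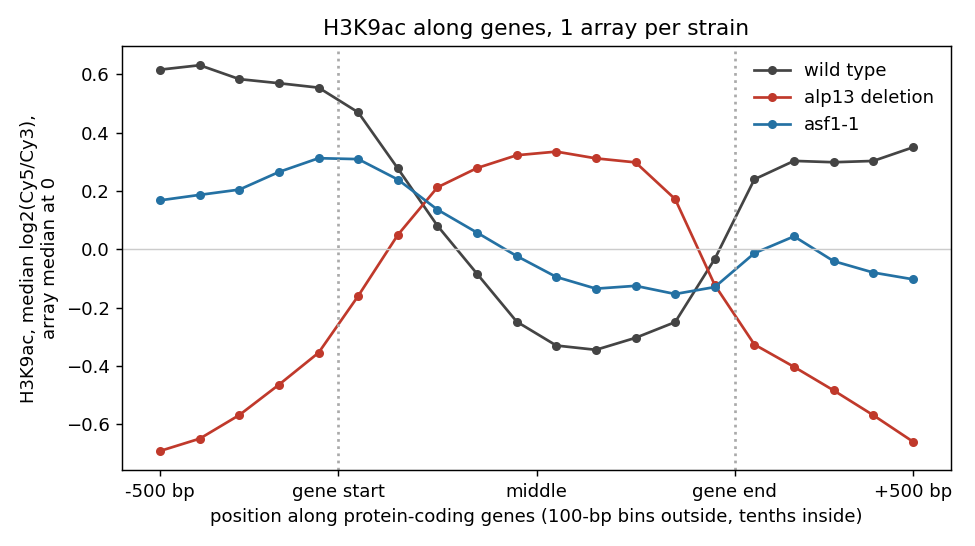
Median log2 ratio of H3K9ac to whole-cell extract (y axis, array median at 0) in 100-bp bins outside and in 10 bins of equal length inside protein-coding genes (x axis), with 1 line per strain and 1 array per strain; flanking bins also hold probes that are upstream of a neighbouring gene. From 100 bp upstream to the gene start wild type lies at 0.55 and the alp13 deletion at -0.35, and between 50% and 60% of the gene length wild type lies at -0.33, asf1-1 at -0.09 and the alp13 deletion at 0.34.

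The comparison of the alp13 deletion with wild type asks where H3K9ac changes when a Clr6 complex subunit is missing. The order along genes turned over: on the alp13 deletion array the median log ratio was 0.31 in the middle part of genes and -0.55 upstream of them. Relative to the array medians, the change was 0.49 in the middle part, where 71.8% of probes were higher, and -1.08 upstream, where 4.05% of probes were higher. It was -0.32 in the first part, 0.26 in the last part, -0.73 downstream and -1.15 elsewhere between genes. The change in the middle part exceeded that upstream by 1.57, and the change over gene bodies exceeded that between genes by 1.21. The latter lay above all 10000 random probe lists, whose highest value was 0.24 with matching on the mean log ratio and 0.51 with matching on Cy3, and in both cases none of 1000 rotations gave a difference as far from 0. With centring on intergenic probes the same changes read 1.67 in the middle part and 0.10 upstream, so the sign of a class depends on the centring and the difference between classes does not.

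Of 893 genes, 137 were higher and 195 lower by at least 1.5-fold in the alp13 deletion, and 35 were higher and 71 lower by at least 2-fold. The split was 310 higher and 72 lower without centring, 705 higher and 3 lower with centring on intergenic probes, 196 higher and 180 lower with the gene median in place of the mean, and 68 higher and 119 lower on Cy5 alone. The gene with the highest change under the naming rule was pho7 (SPBC27B12.11c, chromosome II, 1345112 to 1347974), a transcription factor of the phosphate response, whose mean log ratio rose from -0.82 to 0.74, a change of 1.56 ± 0.36 (SD across 57 probes). Next came tra1 (SPBP16F5.03c, 1894350 to 1905418), a large subunit of the SAGA acetyltransferase complex, with 1.38 ± 0.30 across 221 probes. The others were SPBC24C6.09c (1.26), ist2 (1.15), csc2 (1.11), lsd90 (1.08), the histidine synthesis gene his7 (1.02) and SPBC685.03 (0.92). All 8 had wild-type log ratios at or below 0.01, which a ranking on mutant minus wild type favours.

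The genes with the lowest change under the naming rule had high wild-type H3K9ac, which a ranking on mutant minus wild type favours. They were also all among the 224 shortest genes (129 to 1201 bp), and none of the 8 highest was. The change of a gene rose with its length (rho = 0.694 across 792 genes), so these extremes are not free of gene length. SPBC21B10.15 (1665510 to 1666095) went from 1.93 to -0.45, a change of -2.39 ± 0.47 across 12 probes. SPBC1921.04c (2410996 to 2411404) changed by -1.97 ± 0.13 across 8 probes, and mrpl39 (2700735 to 2701751), which encodes a mitochondrial ribosomal protein, by -1.89 ± 0.33 across 21 probes. The others were SPBC2A9.14 (-1.68), the ribosomal protein gene rpl26 (-1.66), SPBC2A9.13 (-1.65), tam9 (-1.62) and SPBC336.16 (-1.61). SPBC2A9.13 lies inside SPBC2A9.14 on the opposite strand, and their probes cannot be told apart. The alp13 deletion change of these 16 genes kept its sign in each alternative that was run, but on Cy5 alone SPBC685.03 (0.49) was under 1.5-fold, and with centring on intergenic probes the last 5 of the low genes were. Of 272 genes that met the naming rule, 19 were higher and 253 lower. The rule asks that all probes of a gene change one way relative to the array medians. This split thus depends on the rule and the centring, and the calls were 137 higher and 195 lower.

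Ribosomal protein genes were low in the alp13 deletion relative to the array median: 22 of 24 fell by at least 1.5-fold, with a list median of -0.90 that became 0.29 with centring on intergenic probes. No random list matched on the mean log ratio lay as low (percentile 0.0), but against lists matched on gene length the percentile was 7.51. Examples were rpl26, rps1402 (-1.26) and rpl2502 (-1.16), while rpl4302 (-0.45) and rpl1701 (-0.51) did not pass. Of 3 histone genes, hht2, which encodes histone H3 (-1.16 ± 0.30), and hhf2, which encodes histone H4 (-1.20 ± 0.16), fell, and pht1, for the variant H2A.Z, was at -0.54. Their median of -1.16 was at percentile 0.63, turned to 0.03 with centring on intergenic probes, and was at percentile 6.68 with matching on Cy3, 5.14 with matching on length and 5.04 on Cy5 alone. Probes in histone and ribosomal protein genes can bind near-identical copies elsewhere in the genome. The Clr6 complex median was positive in every scaling that was run: the Sin3-family genes pst3 (1.20 ± 0.54) and pst1 (1.07 ± 0.71) rose, png2 was at -0.16, and the median of 1.07 was at percentile 99.91, or 98.17 with matching on length. On Cy5 alone that median was 0.62, at percentile 97.57.

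Glycolysis genes had a median of -0.78 in the alp13 deletion (percentile 3.75; 0.41 with centring on intergenic probes), with eno101 (enolase, -1.51) and fba1 (aldolase, -1.23) below the threshold and tdh1 (-0.33) and pfk1 (0.11) within it. With that centring eno101 and fba1 were under 1.5-fold as well. The list's percentile was 1.85 with normexp, 0.57 on Cy5 alone and 0.88 with matching on length, but 5.46 with matching on Cy3, 8.76 with arrays at 1 spread and 16.1 with the gene median, where the list median was -0.49. All 3 stress response genes fell, with hsp16 at -1.0, gpx1 at -0.66 (-0.49 on Cy5 alone) and trx2 at -0.62 (-0.48 on Cy5 alone), and a median of -0.66 (percentile 9.93; 0.53 with centring on intergenic probes). Among chaperone genes hsp16 fell, and sks2 (-0.49) and mas5 (-0.20) did not pass, with a median of -0.49 (percentile 15.8; 0.70 with intergenic centring). Meiotic genes were split, with spo5 up (0.87; 0.50 on Cy5 alone), rec15 down (-1.12, but positive with intergenic centring), mei4 at 0.49 and rec8 at 0.19. Their median was 0.45 (percentile 81.5). Of 9 mug genes 2 rose, mug93 (0.74) and mug176 (0.63; 0.27 on Cy5 alone), and 4 fell, including mug124 (-1.52) and mug20 (-0.86), with a median of -0.24 (percentile 20.2) that became 0.16 without centring and 0.94 with intergenic centring.

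Of the remaining lists, mating and nitrogen starvation genes had a median of 0.27 (percentile 86.1), and mam1, the M-factor transporter gene, rose by 1.01 ± 0.68 while isp4 (0.42), rep1 (0.21) and gpa1 (0.21) did not pass. Cell cycle genes had a median of 0.54 (percentile 93.6; 99.07 on Cy5 alone). In that list cdc10 (1.02) and mcm2 (0.86) rose and cdc18 was at 0.03. The cyclin-dependent kinase inhibitor gene rum1 fell (-0.72; -0.57 on Cy5 alone), but turned positive with intergenic centring. Sterol and lipid genes had a median of 0.28 (percentile 84.8), with sre1 at 0.91, erg32 at 0.34, erg27 at 0.22 and erg6 at -0.03. Strain marker genes had a median of -0.18 (percentile 26.0; 0.22 without centring and 1.00 with intergenic centring), with his7 up, his3 at 0.18, and his2 and leu1 both at -0.55. In the lists with fewer than 3 measured members, no gene passed the threshold in either mutant apart from the Tf2 elements described below. The HIRA subunit gene slm9 was at 0.48 in the alp13 deletion and 0.02 in asf1-1, clr1 at 0.52 and 0.15, tas3 at 0.16 and 0.04, and the siderophore transporter gene str1 at -0.21 and -0.26. Phosphate uptake, membrane transporter and wtf genes had 0 measured members.

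The comparison of asf1-1 with wild type asks whether the histone chaperone allele changes H3K9ac across the genome. Relative to the array medians, the median change was -0.34 upstream of genes, where 10.2% of probes were higher, and 0.15 in their middle part, where 70.4% of probes were higher. It was -0.07 in the first part, 0.05 in the last part, -0.28 downstream and -0.52 elsewhere between genes. With centring on intergenic probes the upstream change read 0.05 and the middle part 0.55. The change in the middle part exceeded that upstream by 0.49, and the change over gene bodies exceeded that between genes by 0.43, above all 10000 random probe lists, whose highest value was 0.06 with matching on the mean log ratio and 0.16 with matching on Cy3. None of 1000 rotations gave either difference as far from 0. The order along the asf1-1 array itself stayed that of wild type, with 0.22 upstream and -0.05 in the middle part. Weaker enrichment on that array would also shrink the difference between these classes and keep their order. It was not tested for asf1-1, random lists and rotations cannot exclude it, and it stays open here. Centromere 2 did not shrink, with -2.88 on the asf1-1 array against -2.20 on the wild-type array.

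In asf1-1, 15 of 893 genes were higher and 19 lower by at least 1.5-fold, and 0 were higher and 3 lower by at least 2-fold. The split was 50 higher and 10 lower without centring, 209 and 4 with centring on intergenic probes, 53 and 37 with normexp, 19 and 15 with the gene median, and 3 and 10 on Cy5 alone. The highest gene under the naming rule was SPBPB2B2.16c (4497937 to 4499394), within the last 50 kb of chromosome II, which rose by 0.86 ± 0.22 across 29 probes. The splicing helicase gene prp16 (2166225 to 2169933) rose by 0.73 ± 0.29 across 73 probes, vps38 by 0.67 ± 0.22 and the tRNA modification gene dus1 by 0.62 ± 0.24. On Cy5 alone SPBPB2B2.16c was at 0.87, but prp16 (0.54), vps38 (0.40) and dus1 (0.41) were under 1.5-fold. Under 1.5-fold came exo5 (0.58), tam41 (0.57), nop4 (0.56) and crt10 (0.56). The lowest genes under the rule were SPBC21B10.15 (-1.21 ± 0.35), eno101 (2201196 to 2202652; -1.04 ± 0.19 across 29 probes), mug124 (-0.98), SPBC19C7.04c (-0.96), SPBC1921.04c (-0.95), fba1 (1688321 to 1689599; -0.83 ± 0.07 across 26 probes), tdh1 (-0.81 ± 0.63) and SPBC2A9.13 (-0.76; -0.48 on Cy5 alone). With centring on intergenic probes SPBC19C7.04c, SPBC1921.04c, fba1, tdh1 and SPBC2A9.13 were under 1.5-fold. Under the rule, 201 genes passed, 43 higher and 158 lower. As for the alp13 deletion, this split depends on the rule and the centring.

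Glycolysis genes were also low in asf1-1: eno101, fba1 and tdh1, the last for glyceraldehyde-3-phosphate dehydrogenase, fell, and pfk1, for phosphofructokinase, was at 0.20. The median of -0.82 was at percentile 0.0, also with matching on length, and stayed negative with centring on intergenic probes (-0.42), where fba1 and tdh1 were under 1.5-fold. Sterol and lipid genes had a median of 0.26 at percentile 97.53, just outside the central 95%, and inside it in several alternatives, among them 95.57 with matching on Cy3 and 91.71 on Cy5 alone, and no member passed the threshold (erg27 0.49, erg32 0.40, sre1 0.13, erg6 -0.03). Ribosomal protein genes had a median of -0.06 (percentile 25.1; 97.55 with matching on length and 0.32 with normexp, with a median of 0.11 without centring and 0.34 with intergenic centring). Among them 1 of 24 fell, rpl26 (-0.61; -0.47 on Cy5 alone), with rpl35A02 at -0.49, rpl802 at 0.16 and rpl401 at 0.26. Histone genes were at -0.20 (percentile 19.2; 0.19 with intergenic centring), with hht2 at -0.49 and pht1 at -0.19, and Clr6 complex genes at 0.25 (percentile 91.5). The stress response median was -0.31 (percentile 3.96; 0.09 with intergenic centring) and the chaperone median -0.19 (percentile 18.8; 0.21 with intergenic centring), with hsp16 at -0.56.

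Meiotic genes had a median of -0.18 in asf1-1 (percentile 9.36; 0.09 with normexp and 0.22 with intergenic centring), with rec15 down (-0.62; -0.42 on Cy5 alone), mei4 at -0.26 and spo5 at 0.21. The mug genes had a median of -0.15 (percentile 8.61; 0.02 without centring, 0.04 with normexp and 0.25 with intergenic centring), and of these only mug124 passed, with mug100 at -0.39, mug97 at 0.31 and mug57 at 0.15. The genes mug57 and mug97 overlap on opposite strands. Mating and nitrogen starvation genes had a median of 0.13 (percentile 79.1), and mam1 (0.61; 0.44 on Cy5 alone) and gpa1 (0.61; 0.43 on Cy5 alone) rose, with fnx1 at 0.12 and rep1 at -0.15. Cell cycle genes had a median of 0.16 (percentile 86.2; 97.84 with the gene median), and mcm2 rose (0.62; 0.44 on Cy5 alone), with cdc10 at 0.35, cdc18 at -0.27 and rum1 at -0.33. Strain marker genes had a median of 0.09 (percentile 69.9).

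Setting asf1-1 against the alp13 deletion asks how far apart the mutants lie, without the wild-type array. In asf1-1, 145 genes were higher and 78 lower than in the alp13 deletion by at least 1.5-fold, and 25 were higher and 16 lower by at least 2-fold. The median of all genes was 0.08, and -0.16 without centring. The split was 59 and 171 without centring, 0 and 539 with centring on intergenic probes, where that median was -0.71, and 140 and 122 with the gene median. The highest under the naming rule were rpp202 (2127990 to 2128467) at 1.20 ± 0.19 and rpl2502 (2690821 to 2691722) at 1.19 ± 0.19, followed by SPBC32H8.15 (1.18), SPBC21B10.15 (1.17) and SPBC336.16 (1.14). The lowest under that rule were lsd90 (1947985 to 1950255; -1.25 ± 0.16), pho7 (-1.20 ± 0.29), ist2 (-1.18), the meiotic kinase gene mde3 (-1.10) and SPBC15C4.06c (-0.92). Under the rule, 281 genes passed, 260 higher and 21 lower, a split that also depends on the rule and the centring. The median difference was 0.74 over upstream probes, which turned to -0.0467 with centring on intergenic probes, and -0.27 over middle-part probes, which became -1.06.

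Whether both mutants changed the same genes was asked across the 893 genes, which are not independent replicates. The changes correlated with r = 0.677 (rho = 0.657; bootstrap SD 0.020), and 660 genes moved in the same direction. Simulated unchanged groups that share the wild-type array gave r = 0.499 and 596 genes in the same direction on average. The covariance was 0.117 observed and 0.00175 simulated, a difference of 0.115. The simulation holds only the scanner's spot error and leaves out variation between cultures and arrays, so an excess over it does not separate strains from arrays. Both mutants called 10 genes higher, among them mcm2, mam1 and prp16, where independent lists would share 2.30, and 18 lower, among them eno101, fba1, rpl26, rec15 and mrpl39, where independent lists would share 4.15. With centring on intergenic probes 3 genes were lower in the alp13 deletion and 4 in asf1-1, so no more than 3 could be shared. The simulation called 0 in either direction, and 0 genes passed in opposite directions. The 1 wild-type array could not be split, so part of the excess may come from the shared control. With odd-numbered probes for one mutant and even-numbered probes for the other, so that no wild-type spot was shared, r was 0.669 and 0.668. The slope of the asf1-1 change on the alp13 deletion change was 0.291.

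**Figure D2:**
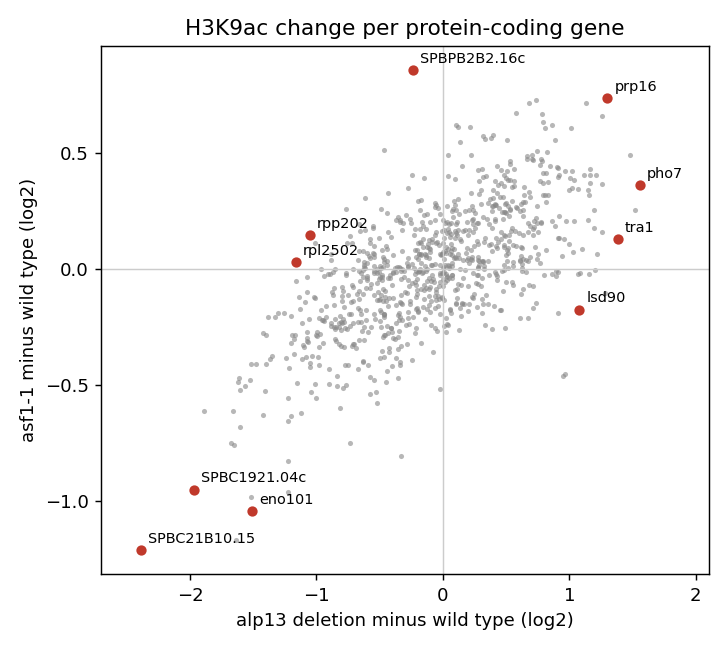
Change in H3K9ac against wild type of 893 protein-coding genes (1 point each, mean over probes, log2) in the alp13 deletion (x axis) and in asf1-1 (y axis), with the 2 highest and 2 lowest genes of each comparison under the naming rule marked; each strain has 1 array and both changes share the wild-type array. Most points lie along a rising band (r = 0.677), while SPBPB2B2.16c (0.86 in asf1-1) and lsd90 (1.08 in the alp13 deletion) lie off it.

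Heterochromatin was compared because Asf1 and Clr6 act at silenced loci. Centromere 2 (array chromosome II, 1597661 to 1650020, 1017 probes) fell in both mutants relative to the array medians, but the alp13 deletion change turned to 0.38 with centring on intergenic probes. The change was -0.80 ± 0.45 in the alp13 deletion and -0.61 ± 0.36 in asf1-1, the latter -0.21 with that centring (SD across probes). No random run of neighbouring probes lay as low in either mutant (percentile 0.0). Those runs came from the rest of the tiled part of chromosome II, which holds genes, while the centromere holds 0. Intergenic probes changed by a median of -1.07 in the alp13 deletion and -0.39 in asf1-1. The percentile thus does not set the alp13 deletion change apart from that of other DNA outside genes. In asf1-1 the fall was deepest in the middle of the centromere, at -1.20 in the 2 kb from array base 1626000 and -1.15 in the 2 kb after it, against -0.64 in the 2 kb from 1606000 and -0.62 in the 2 kb from 1638000. Just left of the centromere both mutants were higher than wild type, with 1.70 in the alp13 deletion and 0.66 in asf1-1 in the 2 kb from 1594000. The Cy3 change in that bin was -0.67 and -0.21. The centromere as drawn starts where the gene rpb1 ends, so this rise was not set apart from that over gene bodies. Further left, in the bins from 1576000 to 1588000, the alp13 deletion change was negative, from -0.89 to -0.17. With arrays at 1 spread the centromere change was -1.28 in the alp13 deletion and -1.06 in asf1-1, and with normexp -1.26 and -0.82. The Cy3 change over the centromere was -0.27 in the alp13 deletion and -0.21 in asf1-1. It reached -2.17 in 2 bins of the alp13 deletion.

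At the right end of chromosome II (4491601 to 4541560, 998 probes) the change was -0.60 in the alp13 deletion (percentile 2.16), which turned to 0.58 with centring on intergenic probes, and -0.06 in asf1-1 (percentile 42.6; 0.34 with that centring and 0.10 without centring). The Cy5 change alone was -0.15 in the alp13 deletion and 0.12 in asf1-1, and the Cy3 change 0.38 and 0.17. The asf1-1 median hid local changes in both directions: 0.95 in the 2 kb from 4500000 and 0.81 in the 2 kb from 4522000, but -0.80 and -1.04 in the last 2 bins from 4538000. The extra contig past its first 12 kb had 584 probes and changed by -0.71 in the alp13 deletion (percentile 2.5; 0.48 with intergenic centring) and by -0.19 in asf1-1 (percentile 6.87; 0.20 with intergenic centring). With normexp these were -1.17 and -0.55. This part of the contig was not uniform: in wild type the 2-kb bins from 12000 and 18000 were at 0.19 and 0.66. Among its bins that were low in wild type, the asf1-1 change ran from -0.65 (from 28000) to 0.12 (from 38000). The mat3 region (2130261 to 2140120, 196 probes) changed by -0.81 in the alp13 deletion (percentile 6.97; 0.37 with intergenic centring) and by -0.08 in asf1-1 (percentile 36.9; 0.32 with intergenic centring). With normexp these were -1.58 and -0.61, and with arrays at 1 spread -1.32 and -0.37.

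**Figure D3:**
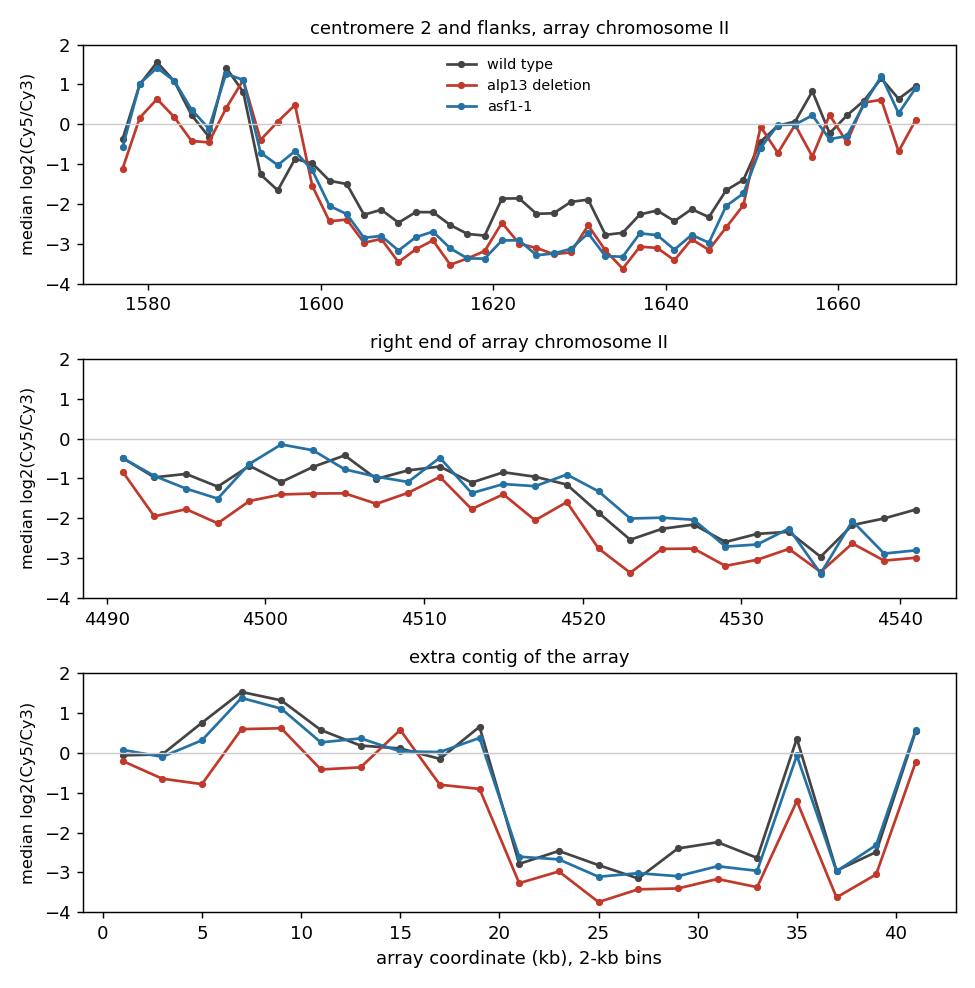
Median log2 ratio of H3K9ac to whole-cell extract (y axis, array median at 0) in bins of 2 kb along the array's own coordinates (x axis, kb) for centromere 2 and its flanks, the right end of chromosome II and the extra contig, with 1 line per strain and 1 array per strain. Over centromere 2 the alp13 deletion (median -3.05) and asf1-1 (-2.88) both lie below wild type (-2.20), while at the chromosome end asf1-1 (-1.38) runs near wild type (-1.24) and the alp13 deletion (-2.00) below it; with centring on intergenic probes the alp13 deletion lies above wild type in both.

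The Tf2 retrotransposons Tf2-9 (1812748 to 1816749) and Tf2-10 (1965390 to 1969390) had median changes of opposite sign in the mutants, which on Cy5 alone was not so. Over their 157 probes the median change was 1.09 in the alp13 deletion (percentile 97.15) and -0.45 in asf1-1 (percentile 2.78; -0.0561 with intergenic centring). With normexp these were 0.38 and -1.08. Both elements passed 1.5-fold in the alp13 deletion and neither did in asf1-1. Their Cy3 signal also moved, by -0.59 in the alp13 deletion and 0.45 in asf1-1, and the Cy5 change alone was 0.47 and 0.01. Probes in these elements can bind the other copies in the genome.

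The rDNA end of chromosome III (array bases 1 to 23120, 457 probes) changed by -1.33 in the alp13 deletion (percentile 0.0; -0.15 with intergenic centring and -0.93 without centring), and by -0.20 in asf1-1 (percentile 10.4; 0.20 with intergenic centring). Its Cy3 signal rose by 1.34 in the alp13 deletion and by 1.97 in asf1-1, and its Cy5 signal changed by 0.08 and 1.64. The neighbouring 536 probes on chromosome III changed by -0.71 in the alp13 deletion, which turned to 0.48 with intergenic centring, and by -0.03 in asf1-1 (0.37 with intergenic centring). Their Cy5 change alone was -0.20 and 0.10, and their Cy3 change 0.36 and 0.13.

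The whole-cell extract channel was compared for genes as well. No gene changed by 2-fold in Cy3 in either mutant, and the Cy3 change ranged from -0.76 to 0.95 in the alp13 deletion and from -0.37 to 0.46 in asf1-1. Across genes, the Cy3 change correlated with the ratio change at r = -0.843 in the alp13 deletion and -0.642 in asf1-1, and the Cy5 change at r = 0.967 and 0.941. The ratio change is the Cy5 change minus the Cy3 change, so these correlations are partly built in. No value for unrelated channels was computed beside them. On Cy5 alone the change in the middle part exceeded that upstream by 1.13 in the alp13 deletion and 0.38 in asf1-1.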

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

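The Cy5 test and the test of the order along the alp13 deletion array below were chosen only after the result was seen; the other tests were not.

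Several items moved in opposite directions in the mutants, and these differences were not tested, since each strain has 1 array. In asf1-1 lsd90 was at -0.18, which turned to 0.22 with centring on intergenic probes, against 1.08 in the alp13 deletion. SPBPB2B2.16c, near the right end of chromosome II, was at 0.86 in asf1-1 and at -0.24 in the alp13 deletion, which turned to 0.95 with centring on intergenic probes. The genes rpp202 (0.14 in asf1-1 and -1.05 in the alp13 deletion), rpl401 (0.26 and -0.77) and rpl802 (0.16 and -0.65) and the histidine synthesis gene his2 (0.18 and -0.55) went the same way as SPBPB2B2.16c, and the alp13 deletion value of each turned positive with centring on intergenic probes. The asf1-1 value of rpl802 turned to -0.23 with normexp. The Tf2 retrotransposons were at -0.45 in asf1-1 (-0.0561 with intergenic centring) and 1.09 in the alp13 deletion. The meiotic list was at -0.18 (0.22 with intergenic centring) and 0.45, and the strain marker list at 0.0882 and -0.18 (1.00 with intergenic centring).

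The authors' deposited value table, which entered no comparison, had mutant columns above its wild-type column in heterochromatin as its values stand. Over centromere 2 the wild-type column had a median of -1.43, the alp13 deletion column -0.55 and the asf1-1 column 2.71. Over the right end of chromosome II the wild-type column was at -1.51 and the asf1-1 column at 2.04, and over the extra contig past its first 12 kb they were at -1.29 and 1.95. The direction of the asf1-1 column is unknown, and it ran against the wild-type, alp13 deletion and asf1-1 arrays (r of -0.533, -0.570 and -0.580). With its sign turned it would lie below the wild-type column in each of these regions. The scanner values of the asf1-1 array had the opposite order over centromere 2, which is the order the column would have with its sign turned. The alp13 deletion column followed the asf1-1 array (r = 0.687) better than the alp13 deletion array (r = 0.528). The table's changes correlated with those from the scanner files at r = -0.0627 for the alp13 deletion and -0.0267 for asf1-1. Within each column neighbouring probes correlated at r = 0.971, 0.963 and 0.955, and no explanation was tested.

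Relative to the array medians, H3K9ac in the alp13 deletion was lower upstream of genes, which turned to 0.10 with centring on intergenic probes, and higher in their middle part, a difference of 1.57 in any centring. On Cy5 alone the difference was 1.13, which argues against the whole-cell extract channel as its whole source. Between probes of equal GC content it averaged 1.47, which argues against GC content. On the alp13 deletion array itself the middle part lay 0.86 above the upstream class, while weaker enrichment alone would only shrink the wild-type difference of -0.84 towards 0. That test restates the reversal already seen. It also takes the Cy3 profile as unchanged, while the Cy3 change was 0.26 upstream and -0.18 in the middle part. No biological explanation was tested. An effect of the missing subunit and error in the single culture or array of either strain that runs along genes both stay open. Without an array of total histone H3, a change in H3 amount stays open as well.

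The asf1-1 changes went the same way as those of the alp13 deletion across genes. With different wild-type probes for each mutant the mean correlation was 0.668, close to 0.677 from all probes, which argues against spot error of the wild-type array. With all arrays scaled to 1 spread, the asf1-1 difference between the middle part and the upstream class was 0.46 against 0.49 unscaled, but this measures probe classes and not the correlation across genes. The correlation itself was 0.580 under that scaling, and no simulation was run on arrays at 1 spread. The part that a larger spread on the wild-type array has in the pattern thus stays open. The scaling used the median absolute deviation (scaled values 0.893 in wild type, 0.772 in the alp13 deletion and 0.777 in asf1-1). By SD the alp13 deletion array was wider than the wild-type array (0.971 against 0.917). Wild-type error over many neighbouring probes and a shared effect of the mutants also stay open and were not tested.

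The Cy3 signal over the rDNA end of chromosome III was higher in both mutants, by a mean of 1.67 over 457 probes. Chromosome II probes of the same GC content were at -0.0477 and those of the same brightness at -0.14, which argues against both as the cause. The number of rDNA copies and the DNA preparation stay open and were not tested.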

How the results depend on the processing

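The alternatives with Cy5 alone, GC adjustment, matching on gene length, the outer 20 kb and rotations were chosen after seeing the data; the others were fixed in advance. Among the leading results, 119 of 200 values stayed within their spread, 78 moved further and 3 called values changed sign. Sign changes of values that were not called are counted only by how far the values moved. Among other results these counts were 256, 73 and 4 of 333, and among named genes 1052, 325 and 27 of 1404. No paired analysis was possible because each strain has 1 array, and no array could be left out in turn for the same reason. The authors' value table was not run as an alternative because its columns do not follow their arrays, and the outer 50 kb because the tiled end of chromosome II is only 50 kb. Of the spots, 99.8%, 99.7% and 99.5% were well above background in wild type, the alp13 deletion and asf1-1, and the other spots limit only the dimmest probes. The cause was not tested for any value below, except that centring adds 1 constant to each array.

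With centring on intergenic probes, 705 genes were higher and 3 lower in the alp13 deletion, 209 and 4 in asf1-1, and 0 and 539 in asf1-1 against the alp13 deletion. The alp13 deletion change turned to 0.38 over centromere 2, 0.58 at the right end of chromosome II, 0.48 (0.4767) on the extra contig and 0.48 (0.4794) on chromosome III past the rDNA, 0.29 for ribosomal protein genes and 0.0299 for histone genes. In asf1-1 the regions were at -0.21, 0.34 and 0.20. Alp13 deletion values of genes whose probes all changed one way that turned positive were SPBPB2B2.16c 0.95, rpp202 0.13, rpl2502 0.0231, rpl4302 0.74, rpl401 0.42, rpl802 0.53, rpl35A02 0.28, pht1 0.64, hht2 0.0299, gpx1 0.53, hsp16 0.18, rec15 0.0609, mug20 0.33, rum1 0.46, his2 0.635 and leu1 0.64. Of the other named genes tdh1, rpl1701, trx2, mas5, sks2, mug100, png2 and erg6 also turned positive. In asf1-1 the former were SPBC32H8.15 0.19, rps1402 0.21, pht1 0.20, hhf2 0.19, trx2 0.0912, mug20 0.15, mug100 0.0058, rum1 0.0655 and cdc18 0.1251, and the latter ist2, lsd90, SPBC15C4.06c, rpl1701, gpx1, sks2, mei4, mug93, mug176, rep1, erg6, his3 and leu1. Without centring the counts were 310 and 72, 50 and 10, and 59 and 171. The alp13 deletion change was then -0.39 over centromere 2, -0.19 at the right end and -0.30 on the contig, the asf1-1 change -0.45, 0.10 and -0.0296, and SPBPB2B2.16c in the alp13 deletion 0.17.

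With normexp, 53 genes were higher and 37 lower in asf1-1. Gene bodies exceeded intergenic probes by 1.36 in the alp13 deletion and 0.51 in asf1-1. Centromere 2 was at -1.26 and -0.82, the contig at -1.17 and -0.55, and the correlation of both mutants' changes was 0.733. With arrays at 1 spread, 23 genes were higher in asf1-1, gene bodies exceeded intergenic probes by 1.42 in the alp13 deletion, and the middle part exceeded the upstream class by 1.72 in the alp13 deletion and 0.46 in asf1-1. Centromere 2 was then at -1.28 and -1.06, the right end at -0.96 and -0.31, the contig at -1.16 and -0.48, and the correlation was 0.580. At 2-fold the counts were 35 and 71, 0 and 3, and 25 and 16. With the gene median 122 genes were lower in asf1-1 than in the alp13 deletion. With the second part of genes on a split at the midpoint, the difference from upstream was 1.46 and 0.44. In asf1-1 1 list lay outside the central 95% in place of 2 with a minimum of 1 or 5 probes, Cy3 matching, arrays at 1 spread, Cy5 alone or GC adjustment.

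With Cy5 alone the counts were 68 and 119, 3 and 10, and 66 and 45. Gene bodies exceeded intergenic probes by 0.92 and 0.34 and the middle part the upstream class by 1.13 and 0.38, while the wild-type middle part lay 0.49 above upstream, in a comparison of different probe sequences. Centromere 2 was at -1.15 and -0.85, the right end at -0.15 and 0.12, the rDNA end at 0.0751 in the alp13 deletion, and SPBPB2B2.16c at 0.071 in the alp13 deletion, and the correlation was 0.638. With GC adjustment, gene bodies exceeded intergenic probes by 1.03 and 0.36, the middle part the upstream class by 1.29 and 0.39 (wild type -0.69), and the correlation was 0.652.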

Other observations

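The tests here were all chosen after the data had been seen, and no explanation is offered for the values. Gene length separated genes in the alp13 deletion. Among the 224 shortest genes (129 to 1201 bp) the median wild-type log ratio was 0.39, the alp13 deletion change -0.69 and the asf1-1 change -0.15. Among the 223 longest (2455 to 11069 bp) these were -0.23, 0.50 and 0.12. In the middle part of genes, the alp13 deletion change went from -0.68 in the shortest genes to 0.95 in the longest. The middle part of the shortest genes was shorter than the sheared DNA fragments. Values there can thus include signal from the flanks, and this limit cannot be told apart from a change with gene length. It also bears on the shorter genes in the correlation with length. Across 792 genes, which are not independent replicates, the middle-part change correlated with length at rho = 0.785 in the alp13 deletion and 0.483 in asf1-1. With centring on intergenic probes all these changes move up by the same amount within an array, and their order stays.

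Between genes, H3K9ac followed the direction of the neighbouring genes. In 200 divergent regions, which hold 2 gene starts, the wild-type median was 0.69, in 290 tandem regions 0.36, and in 64 convergent regions -0.15. The alp13 deletion change was -1.31, -0.92 and -0.69 in the same order, and the asf1-1 change -0.43, -0.32 and -0.20. On the alp13 deletion array the log ratio was -0.71, -0.66 and -0.78, so the wild-type order was no longer seen.

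At centromere 2 the alp13 deletion had less Cy3 signal in 2 places. The change was -2.17 in the 2 kb from array base 1618000 and -2.17 in the 2 kb from 1632000, where asf1-1 was at -0.33 and -0.38. Whether these 2 places share sequence with each other or with other centromeres was not tested. On the extra contig, the 2 kb from base 34000 had a wild-type median of 0.36 between neighbours at -2.64 and -2.96, and was at -1.21 in the alp13 deletion and -0.06 in asf1-1. The segments that were not placed on the reference are given as median changes against wild type. These were 0.87 in the alp13 deletion and 0.39 in asf1-1 over 99 probes of array chromosome I (2195400 to 2200359). They were 0.85 and 0.16 over 59 probes of chromosome III (1724400 to 1727359), and 0.68 and 0.34 over 39 probes of chromosome III (1838900 to 1840859).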
